A study of Pseudomonas qingdaonensis with 4 samples.

How the data were processed

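RNA of the bacterium Pseudomonas qingdaonensis strain S-1 was sequenced from 4 genotypes, with 1 library per genotype. The groups follow the genotype labels: the S-1 strain itself (WT), S-1 given the dnd gene cluster of strain Pf0-1 (dnd), S-1 given a dam gene cluster (dam), and S-1 given both (dnd_dam). The dnd genes of bacteria encode the enzymes that replace an oxygen of the DNA backbone with sulfur (phosphorothioation), and dam genes encode an adenine methyltransferase. Per the labels' protocols, total RNA was extracted with TRIzol and libraries were made with the NEBNext Ultra RNA kit for Illumina. Growth conditions and the growth phase at harvest are not given in the sources used here.

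Per the submitters' processing notes, the tools were CASAVA 1.8, fastp, HISAT2 2.0.5 for alignment, featureCounts 1.5.0-p3 for counting and DESeq2 1.20.0. The genome build and the strand setting of the counting are not given in the sources used here. The deposited count table holds whole-number read counts for 5346 protein-coding genes in 1 column per library, with the position, strand and length of each gene and a description. Its lengths are all multiples of 3, so they are coding lengths. The deposited FPKM table holds the same genes. Each FPKM value equals the count divided by coding length and library total, times 1 constant per library (0.9756 for WT, 0.9316 for dnd, 1.0276 for dam and 1.0487 for dnd_dam), with a largest deviation of 5.1e-10, so it carries no information beyond the counts and a scaling. The number of columns that match no sample is 0.

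Gene symbols were taken from the description of the best Swiss-Prot match that the count table gives. A product was given for 3717 genes and a symbol for 3670, and 3290 had a product other than hypothetical or uncharacterized and could be named. A symbol is therefore that of the closest curated protein, often from another organism, and several genes can carry the same symbol. Identifiers and coordinates on chromosome 1 are those of the table. Without a stated strand setting, reads of a gene and of one overlapping it on the other strand cannot be told apart, and reads of near-identical copies may have been split.

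From the counts, log2 ratios of CPM (counts scaled to library size) were computed after TMM scaling (edgeR 4.0.16 in R 4.3.3), with a prior count of 2. The scaling factors were 1.019 for WT, 1.065 for dnd, 0.967 for dam and 0.953 for dnd_dam. A gene was compared when the higher of both libraries had at least 50 counts, and for the interaction when any library had. The interaction is the log2 ratio of dnd_dam to dam minus that of dnd to WT. With 1 library per genotype there is no replicate check, so no test was made of any pair of libraries: genes at least 2-fold apart were counted as a description. Intervals are exact 95% Clopper-Pearson intervals of the ratio of counts, combined in quadrature for the interaction, and cover counting error only. A gene at 0 was set against a floor of 3 counts per gene, which is 0.598 CPM in WT, 0.584 in dnd, 0.596 in dam and 0.69 in dnd_dam, and is given only as at least so many fold lower.

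Before the data were examined, the comparisons, the settings to vary, 25 gene lists built from symbols and products, and the rule for named genes were fixed. The rule took the 8 highest and 8 lowest log2 ratios of each comparison with WT (the 4 highest and 4 lowest of the others) among nameable genes that were compared and at least 2-fold apart, the 2 such members of each list farthest from 0, and every gene with a dnd, ssp or dam symbol. After the data were seen, the 8 lowest genes outside a block of genes at 0 were added, and other genes are named in the text as neighbours or list members. On inspection of the products, 125 accidental matches were taken out of 15 lists, leaving 1066 memberships. A list's median log2 ratio is given with its percentile among 10000 random lists of as many genes, matched on mean expression and drawn outside the block, which describes these libraries only. Lists with fewer than 5 compared genes are given as values.

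The ratio calculation was tested on simulated data with known folds for dnd against WT. With counting error alone (4131 genes), 52.2% of genes simulated at 2-fold and 100% of those at 4-fold or 8-fold passed 2-fold, as did 0.0% of unchanged genes, and the interval held the true ratio for 95.6% of unchanged genes. With a spread of 0.25 log2 units per library added (4161 genes), 1.14% of unchanged genes passed 2-fold and the interval held the true ratio for 47.1% of them. Of 200 unshifted lists of 40 genes, 5.5% and 2.5% fell outside the 2.5th to 97.5th percentile in these runs, and a list shifted 2-fold stood at percentile 100. These lists held scattered genes with independent noise, so the runs do not cover lists whose members move together. An additive model over the 4 libraries (dnd and dam terms, no interaction, 1 residual degree of freedom) was fitted with edgeR's quasi-likelihood test and with DESeq2 1.42.0 at an adjusted p of 0.05. In simulated data of 4310 genes for its dnd term, edgeR called 40.3% of 2-fold, 100% of 4-fold and 100% of 8-fold genes, with 4.2% of 167 calls false. DESeq2 called 32.8%, 98.5% and 100% of them, with 1.3% of 156 calls false. The simulated data held no dam effect, no interaction and the same dispersion for every gene, so the model's assumption was met by construction. These shares of false calls therefore do not carry over to the real libraries. Other steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

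The settings varied were the scaling (DESeq2 size factors, or library size alone), the low-count filter, the fold threshold, the prior count, the unit (log2(FPKM + 1)), and leaving out the 10 genes with the most counts. Added after the data were seen were the counts without the block of genes at 0, a 2-fold limit beyond the counting interval, lists shifted along the chromosome in place of random lists, lists as matched, and the additive model. The introduced dnd and dam genes were not analysed here, since the table names none, so the labels could not be checked by them.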

Results

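Total RNA of 4 strains was sequenced, 1 library each: the S-1 strain (WT), S-1 carrying the dnd cluster (dnd), S-1 carrying dam (dam) and S-1 carrying both (dnd_dam). The labels form a factorial design of both DNA modification systems, and the series title names changes in coexisting phosphorothioates and methylation as its subject. The libraries held 4922055 counts (WT), 4826071 (dnd), 5201862 (dam) and 4560472 (dnd_dam) over 5346 genes. Depths were close to one another, and 22, 118, 28 and 134 genes were at 0 in that order. The share of counts from ribosomal protein genes was 21.8% in WT, 17.5% in dnd, 21.6% in dam and 20.5% in dnd_dam. Log2 levels of the 3993 genes outside the block described next were closest between dam and dnd_dam (r = 0.971 across genes, which are not independent replicates) and farthest apart between WT and dnd (r = 0.912). There was no replicate of any genotype, so every value below describes a library, and its interval covers counting error only. Coordinates are those of the deposited table for chromosome 1, and the genome build is not given in the sources used here.

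Both libraries with the dnd cluster had 0 counts over a run of 94 neighbouring genes between positions 1464237 and 1571844 of chromosome 1, a stretch of 107.6 kb. The same genes held 26300 counts in WT and 28716 in dam, and 93 of them were above 0 in each of these libraries. The summed block was therefore at least 8988-fold lower in dnd and at least 7597-fold lower in dnd_dam than in WT, with a floor of 3 counts over the block. Between dam and WT it differed by 0.12 log2 units (0.10 to 0.15). Only 23 of the 94 genes had a Swiss-Prot match. They included sss (P.putida.S1GL001340, 1464237 to 1465490), a tyrosine recombinase of the XerC family and the first gene of the run, with 492 counts in WT and 551 in dam. Genes matched to the replicative helicase dnaB (P.putida.S1GL001430), the type II secretion gene epsE (P.putida.S1GL001410) and the cobalamin receptor gene btuB (P.putida.S1GL001373) had 164 and 99, 284 and 350, and 238 and 440. These names are of the closest match and do not show that the strain has no other copy. A further epsE (P.putida.S1GL005082) outside the block had 69, 42, 27 and 17 counts in WT, dnd, dam and dnd_dam. Other block genes were matched to a shufflon-specific recombinase (rci), a shufflon protein and a plasmid DNA topoisomerase I. A pair of TonB-dependent receptor genes, both named yncD (P.putida.S1GL001367 and P.putida.S1GL001368), the twitching motility gene pilT and the cytochrome bd oxidase genes cydA and appB also lay there. The genes on either side had counts in all 4 libraries: the left neighbour queC, a queuosine synthesis gene, had 800, 547, 581 and 669 counts in WT, dnd, dam and dnd_dam, and the right neighbour P.putida.S1GL001434 had 193, 155, 113 and 92. Outside the block, 0 of the 4020 genes with at least 50 WT counts were at 0 in either dnd library, and the next longest run of genes at 0 in both held 2 genes.

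**Figure D1:**
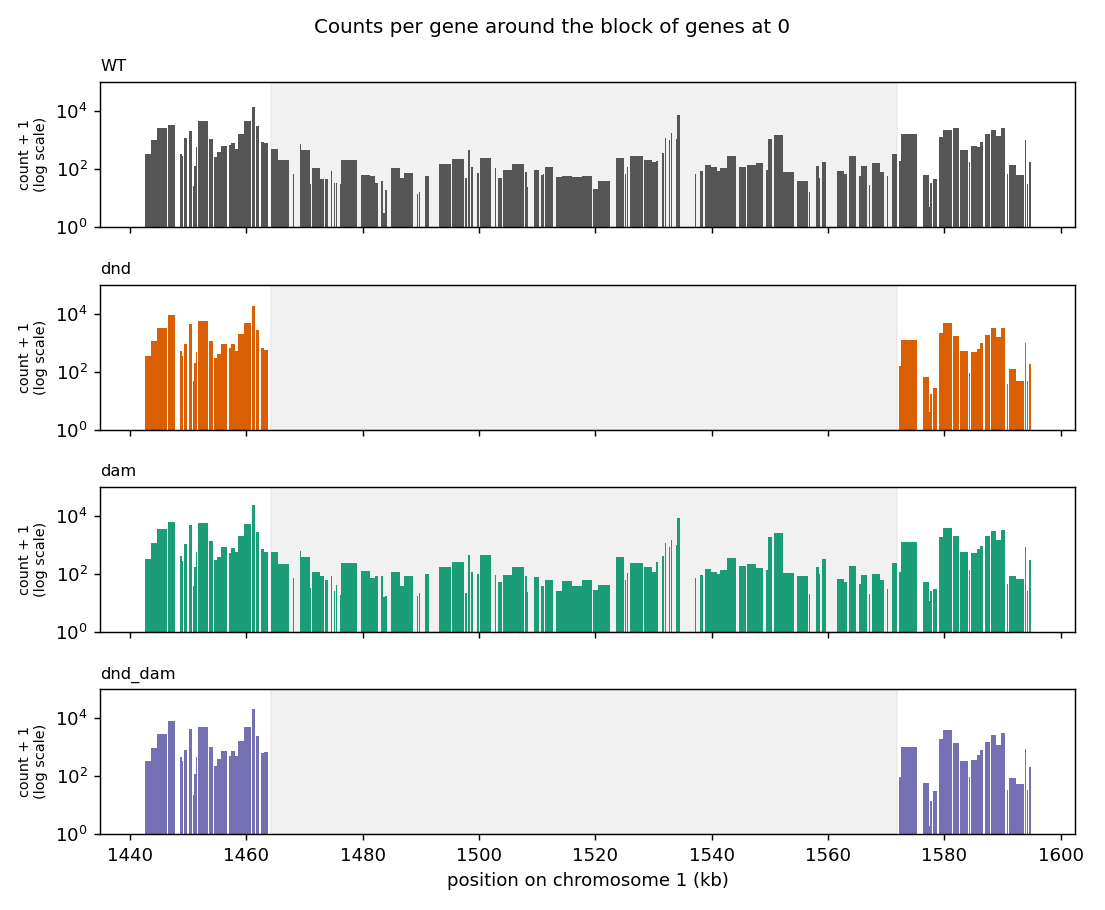
Counts per gene (count + 1, log scale) along chromosome 1 in kb, 1 panel per library, with bars as wide as the genes and the block of 94 genes shaded. WT and dam have counts through the block, which sums to 26300 and 28716, while dnd and dnd_dam have 0 counts there and counts on both sides.

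The comparison of dnd with WT asks how the transcript levels of S-1 differ when the dnd cluster is added. The genes of glycolate use stood highest in the dnd library: glcG (P.putida.S1GL003353, 3740733 to 3741122) had 7 counts in WT and 1004 in dnd, a log2 ratio of 6.76 (6.08 to 8.45). The glycolate oxidase subunit genes glcD, glcE and glcF stood at 6.38 (5.98 to 6.97), 6.37 and 6.26, and glcB, which encodes malate synthase G, at 6.21 (5.87 to 6.67). Next came the genes of an amino acid uptake system matched to the glutamine transporter, with glnQ (P.putida.S1GL000173) at 4.65 (4.02 to 5.99), glnH at 4.19 and glnP at 4.04. On the lower side, outside the block, was a run of 9 genes from 3698792 to 3709323 that held 28726 counts in WT, 469 in dnd, 399 in dam and 412 in dnd_dam. Its members included the catalase-related peroxidase gene srpA (P.putida.S1GL003315), with a log2 ratio of -7.64 (-8.12 to -7.31), the porin gene nicP (P.putida.S1GL003317) at -6.86 and the sigma factor gene sigR (P.putida.S1GL003314) at -5.69. Within the block, sss was at least 168-fold, epsE at least 97.1-fold, btuB at least 81.3-fold and dnaB at least 56.0-fold lower than in WT.

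Genes for taking up and using sulfur formed the list with the most members higher in dnd. Of 79 compared genes, 27 were at least 2-fold higher and 4 lower, and the median of 0.33 stood at percentile 99.98 of random lists. The taurine permease gene tauC (P.putida.S1GL000195) was at 3.90 (3.24 to 5.23), the sulfonate-binding protein gene ssuA (P.putida.S1GL002011) at 3.82, and cysNC (P.putida.S1GL004364), which activates sulfate, had 888 counts in WT and 7910 in dnd. Among 31 genes of the TCA cycle and glyoxylate shunt, 11 were higher and 1 lower (median 0.90, percentile 100). The exception was mqo1 (P.putida.S1GL003655), a malate:quinone oxidoreductase, at -3.51 (-3.67 to -3.36). Of 27 genes of branched-chain and aromatic compound breakdown, 11 were higher and 0 lower (median 0.61, percentile 99.99), led by the isovaleryl-CoA dehydrogenase gene Ivd (P.putida.S1GL003077) at 3.24. The flagella and chemotaxis list had 7 members higher and 7 lower of 89 (median 0.39, percentile 100), with a chemoreceptor gene mcpS (P.putida.S1GL002900) at 2.34. Respiration genes outside the block (median 0.35, percentile 99.95, or 97.25 among shifted lists) and amino acid synthesis genes (0.27, percentile 99.59) also lay above most random lists.

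Iron uptake and storage genes lay on the lower side in dnd: of 93 compared, 0 were at least 2-fold higher and 21 lower. The lower ones include 3 block genes at 0. The median outside the block stood at percentile 0.00. Within the run of 9 genes, the iron-related regulators fecI and fecR stood at -3.89 and -3.31. All 53 ribosomal protein genes were within 2-fold, with a median of -0.36 (percentile 0.00, or 0.71 among lists shifted along the chromosome). Drug efflux genes had 0 higher and 5 lower of 35 (median -0.33, percentile 0.10), among them the pump genes bepF at -2.51 and bepE at -1.96. Prophage genes had 0 higher and 1 lower of 11 (median -0.52, percentile 0.49). Among 29 osmotic and stationary-phase genes, 6 were higher and 4 lower, with the choline transporter gene betT at -2.87 and osmY, a periplasmic osmotic stress protein gene, at 2.01. The 46 SOS and DNA repair genes held 0 at least 2-fold apart (median 0.04, percentile 30.02), and so did the 4 restriction and methylation genes mcrA, hsdS, hsdM and hsdR. Of 4255 compared genes, 323 were at least 2-fold higher and 252 lower in dnd, and 181 of the latter lay outside the block; with no low-count filter, 374 were higher and 378 lower. Of 22 lists, 4 stood below percentile 2.5 and 6 above 97.5, or 4 and 5 among lists shifted along the chromosome. Lists of independent genes would give 1.1 in all. Neighbouring members often moved together, so that number is no measure of chance here.

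The comparison of dam with WT asks the same of the dam cluster. A group of neighbouring genes for amine breakdown stood highest: gabT (P.putida.S1GL002482, 2747370 to 2748662), a 4-aminobutyrate aminotransferase gene, had 29 counts in WT and 4070 in dam, a log2 ratio of 7.03 (6.60 to 7.71). The dehydrogenase gene davD next to it (P.putida.S1GL002483) was at 6.66 (6.23 to 7.34), the regulator gene doeX at 4.18, and potD-A (P.putida.S1GL002486), a polyamine-binding protein gene, at 3.66 (3.54 to 3.79). These genes were above WT in dnd too, though less so: gabT had 153 counts there, davD 157, doeX 69 and potD-A 1742, against 29, 29, 31 and 536 in WT. The glutamylputrescine synthetase gene puuA stood at 2.94, the short-chain fatty acid transporter gene atoE at 3.13 and its neighbour lpsJ, a ketoacid transferase gene, at 2.88. The run of 9 genes high in WT was low here too, with srpA at -8.72 (-9.50 to -8.26), nicP at -6.50 and sigR at -6.22. The next lowest was norM (P.putida.S1GL005186, 5764096 to 5765481), a multidrug efflux gene, with 772 counts in WT and 79 in dam (-3.26, interval -3.65 to -2.96).

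The list of TCA cycle genes again stood at percentile 100 in dam, with 7 of 31 members higher, 2 lower and a median of 0.54. The isocitrate dehydrogenase gene icd (P.putida.S1GL003247) was at 1.83 (1.66 to 2.02) and the succinyl-CoA ligase gene sucD (P.putida.S1GL001837) at 1.52. Amino acid synthesis genes had 5 of 62 higher and 0 lower (median 0.33, percentile 99.99), led by ilvC and ilvH of branched-chain synthesis at 1.87 and 1.48. Respiration genes (median 0.38, percentile 99.98), flagella and chemotaxis genes (0.26, percentile 99.95) and fatty acid genes (0.21, percentile 98.36, or 0.14 by library size alone) lay above most random lists. The median of 12 prophage genes was -0.56 (percentile 0.08), with 0 of them 2-fold apart, and that of 28 chaperone and protease genes -0.12 (percentile 0.36, or 11.41 among shifted lists), or -0.19 by library size alone. Of 98 iron genes 1 was higher and 10 lower (percentile 3.24, or 0.07 among shifted lists), and of 71 sulfur genes 3 were higher and 3 lower (percentile 9.80), with cysNC at 1.31 and the S-adenosylmethionine synthase gene metK at 1.26. The ribosomal protein median was 0.06, and -0.02 when libraries were scaled by size alone. Of 4207 compared genes, 158 were higher and 117 lower in dam, so that 57.5% of these were higher; scaled by library size alone, 47.3% were, and with no low-count filter 44.5%.

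**Figure D2:**
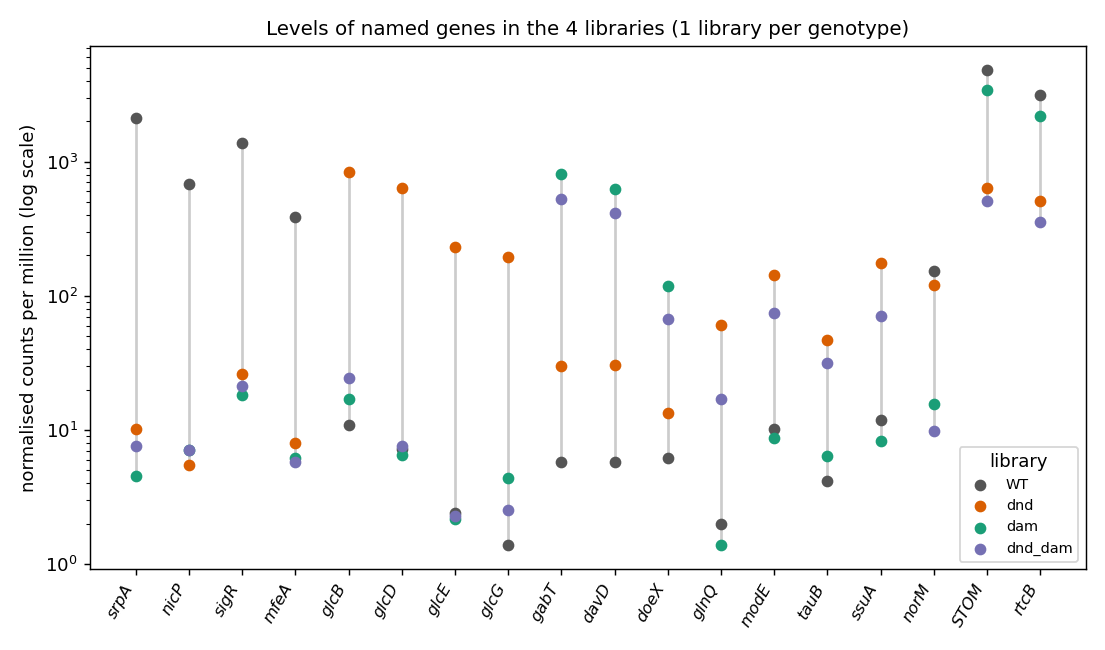
Normalised counts in CPM (log scale) of 18 genes in the 4 libraries, 1 point per library, with a grey line from the lowest to the highest. srpA, nicP, sigR and mfeA are high in WT alone, the glc genes in dnd alone, and gabT, davD and doeX are highest in the libraries with dam. gabT is at 808.9 in dam and 528.6 in dnd_dam against 5.78 in WT and 29.76 in dnd.

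The comparison of dnd_dam with WT takes both clusters together. The amine genes that stood highest in dam were high here too, with gabT at a log2 ratio of 6.42 (5.99 to 7.10), davD at 6.06 and potD-A at 3.60. So were sulfur genes that stood out in dnd, with tauC at 3.15 (2.45 to 4.50) and tauB (P.putida.S1GL000196) at 2.79. On the lower side were srpA at -8.04 (-8.65 to -7.62), norM at -3.91 (-4.44 to -3.52), and a pair of neighbours with high counts in WT: STOM (P.putida.S1GL004704, 5232977 to 5234122), matched to a membrane protein of the stomatin family, had 24246 counts in WT and 2195 in dnd_dam (-3.26), and the RNA ligase gene rtcB (P.putida.S1GL004703) 15639 and 1534 (-3.14). The block genes sss and epsE were at least 142-fold and 82.0-fold lower.

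TCA cycle genes had 12 of 31 members higher and 1 lower in dnd_dam (median 0.84, percentile 100), with sucD at 1.67 and mqo1 at -2.43. Sulfur genes had 17 of 75 higher and 2 lower (median 0.20, percentile 97.14, or 0.11 by library size alone). Prophage genes had 0 of 11 higher and 7 lower (median -1.16, percentile 0.00), among them the phage baseplate genes I (P.putida.S1GL001282) at -1.59 and W (P.putida.S1GL001280) at -1.57. Genes for exopolysaccharide had 3 of 21 higher and 0 lower (median 0.41, percentile 99.44), and these were genes for making alginate, such as algD (P.putida.S1GL002057) at 2.28 (1.95 to 2.69) and alg44 at 2.07. Iron genes had 3 of 95 higher and 11 lower, the latter including 3 block genes at 0 (median -0.33 outside the block, percentile 1.85). Drug efflux genes had 0 of 35 higher and 9 lower (-0.27, percentile 0.45), including norM and acrA. Medians of amino acid synthesis (0.37), branched-chain and aromatic breakdown (0.44), respiration (0.39), fatty acid (0.30) and oxidative stress genes (0.33) stood between percentiles 99.02 and 99.98. The ssp genes, named for stringent starvation, were the only ones with a dnd, ssp or dam symbol: sspB was at 1.02 and sspA at 0.87, with sspA at 1304, 1804, 1717 and 2062 counts in WT, dnd, dam and dnd_dam. Of 4164 compared genes, 231 were higher and 313 lower, 242 of the latter outside the block.

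The comparison of dnd_dam with dnd sets libraries with and without dam side by side where dnd was present. The glc genes were lower in dnd_dam, with glcE at a log2 ratio of -6.42 (-7.71 to -5.77), glcD at -6.30, glcG at -6.06 and glcF at -5.62, so that their counts in dnd_dam (10 for glcE, 33 for glcD) were near those of WT (12 and 36). The genes gabT and davD were higher at 4.13 (3.91 to 4.40) and 3.74, doeX at 2.29, and the asparaginase gene ansA (P.putida.S1GL004738) at 2.56. Sulfur genes had 13 of 79 members lower and 1 higher (median -0.30, percentile 0.00), iron genes 0 of 77 lower and 6 higher (0.19, percentile 100), and flagella and chemotaxis genes 5 of 87 lower and 1 higher (-0.25, percentile 0.00). The ribosomal protein median was 0.38 (percentile 99.94), the oxidative stress median 0.25 (percentile 99.81) and the prophage median -0.70 (percentile 0.00). Scaling by library size alone moved the median of all genes to -0.17, and these lists kept their sign under it, with medians of 0.03 for iron, 0.09 for oxidative stress, 0.22 for ribosomal protein, -0.46 for sulfur, -0.41 for flagella and chemotaxis and -0.86 for prophage genes. Of 4057 compared genes 78 were higher and 185 lower, so that 29.7% were higher, or 16.4% by library size alone.

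The comparison of dnd_dam with dam sets libraries with and without dnd side by side where dam was present. Here too the block was at 0 only in the library with dnd, which is dnd_dam, so effects of dnd and of the block cannot be told apart. Highest were genes that were also high in dnd against WT: the ornithine cyclodeaminase gene arcB (P.putida.S1GL003570, 4014604 to 4015650) at a log2 ratio of 3.44 (3.02 to 4.04), glnQ at 3.28, the molybdenum regulator gene modE (P.putida.S1GL002591) at 3.04 and ssuA at 3.01. The lowest were block genes, with sss at least 159-fold, btuB at least 127-fold and epsE at least 101-fold lower than in dam. Sulfur genes had 14 of 74 higher and 1 lower (median 0.11, percentile 99.18), and branched-chain and aromatic breakdown genes 5 of 26 higher and 0 lower (0.29, percentile 99.93). Exopolysaccharide genes (0.38, percentile 100) and TCA cycle genes (0.21, percentile 99.98, or 97.36 among shifted lists) lay above most random lists, while prophage genes (-0.56, percentile 0.09), flagella and chemotaxis genes (-0.16, percentile 0.00) and pili genes outside the block (-0.49, percentile 0.54, or 2.80 among shifted lists) lay below. Of 4086 compared genes, 100 were higher and 152 lower, and 81 of the latter lay outside the block.

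The interaction compares the dnd difference with dam present and without it. The single WT library enters it, so genes that stand apart in WT alone also give an interaction, and the causes cannot be told apart. TCA cycle genes, for example, had medians of 0.90, 0.54 and 0.84 against WT in dnd, dam and dnd_dam. The highest values belonged to the run of 9 genes high in WT alone, with srpA at 8.33 (7.49 to 9.33), nicP at 6.86, sigR at 5.91 and mfeA at 5.44, and the lowest to the genes high in dnd alone, with glcG at -7.46 (-9.58 to -6.24), glcE at -6.30, glcD at -6.18 and glcF at -5.70. Of 99 iron genes 17 were higher and 1 lower (median 0.38 outside the block, percentile 100), and of 36 drug efflux genes 7 were higher and 3 lower (0.26, percentile 99.79). Sulfur genes had 0 of 79 higher and 16 lower, with a median of -0.16 at percentile 10.47. The medians of flagella and chemotaxis (-0.41), TCA cycle (-0.49) and amino acid synthesis genes (-0.29) stood at or below percentile 0.06, and that of ribosomal protein genes (0.35) at 99.79. Library size alone moved the median of all genes to -0.14 and left the signs of these lists as they were, with drug efflux genes at 0.17 and sulfur genes at -0.24. Of 4310 genes, 171 were at least 2-fold higher and 297 lower.

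Genes that stood apart with dnd did so in part both without and with dam. In both comparisons the block was at 0 only in the library that carried dnd, so what they share may follow the block or the dnd cluster. The modE, glnQ, tauC and ssuA genes were high in both comparisons and STOM low in both, while the glc genes were high in the first alone. Over 4232 genes outside the block, which are not independent replicates, the log2 ratios of dnd to WT and of dnd_dam to dam correlated at r = 0.418, and these comparisons share no library. Both had 70 genes at least 2-fold higher in common (8.4 for independent lists), 38 lower in common (4.0), and 5 at least 2-fold apart in opposite directions. For dam, the ratios without and with dnd correlated at r = 0.236, with 24 genes higher in both (3.1 for independent lists), 27 lower in both (5.4) and 12 opposite. The dnd and dam differences from WT share the WT library: r was 0.518, against 0.501 in 100 simulations of unchanged genes sharing that library, and the covariance was 0.256 against 0.081. They had 78 genes higher in common and 47 lower, where independent lists give 12.1 and 5.1 and the simulations 4.7 and 2.8. Part of this excess may come from the shared library. The simulations used a spread of 0.265 log2 units per library and gave fewer common genes than independent lists. They therefore cannot size the part of the overlap or covariance that the shared library makes.

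**Figure D3:**
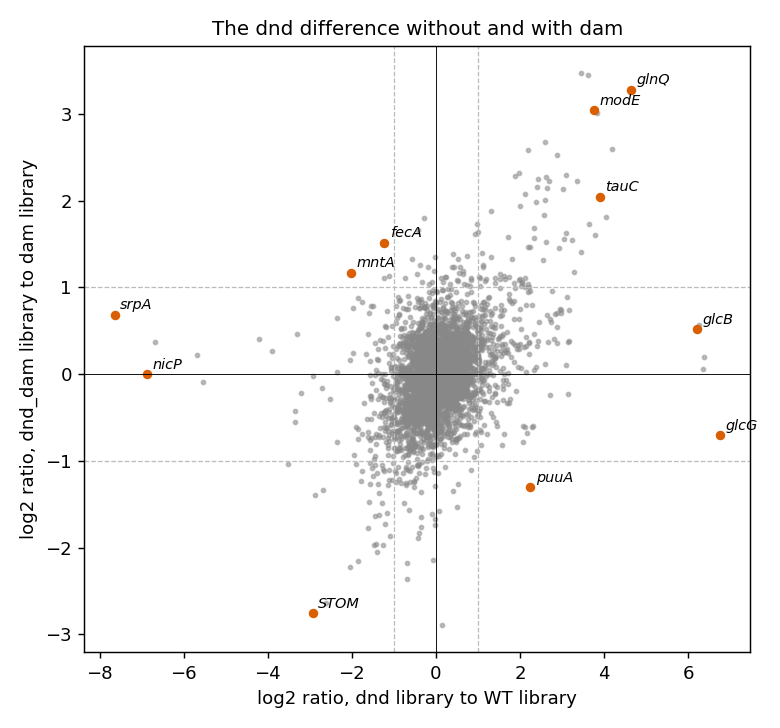
Log2 ratio of dnd to WT (horizontal) against that of dnd_dam to dam (vertical), 1 point per compared gene outside the block, with dashed lines at 2-fold and 11 genes coloured and named. glnQ, modE and tauC lie high on both axes and STOM low on both, while glcB and glcG are high, and srpA and nicP low, on the horizontal axis alone.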

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

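Every test in this part was chosen after the result it bears on had been seen.

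For 16 genes, libraries with and without one cluster differed at least 2-fold in one direction where the other cluster was absent. Where it was present, they differed at least 2-fold in the other direction. This contrast was not tested, since each value rests on 4 single libraries. The values are the log2 ratio with the other cluster minus that without it. For the dnd difference they were 3.18 for the manganese-binding protein gene mntA (265, 66, 54 and 107 counts in WT, dnd, dam and dnd_dam), 2.74 for the ferric citrate receptor gene fecA (1620, 709, 485 and 1201), -3.56 for puuA (34, 174, 275 and 95), 2.35 for P.putida.S1GL000847 and 2.24 for P.putida.S1GL003324. For the dam difference they were 2.94 for the hexuronate transporter gene exuT (902, 88, 332 and 213), 2.90 for its neighbour gatA, 2.28 for the superoxide dismutase gene sodA, 2.48 for mqo1, 2.08 for PA0567 and again 2.74 for fecA. On the other side were -7.46 for glcG, -2.96 for the hydroxybutyrate dehydrogenase gene hbdH1, -2.51 for the serine dehydratase gene sdaA, -2.43 for the glycine cleavage gene gcvP1, -2.35 for the aldehyde dehydrogenase gene aldA and -2.11 for ssuB. The dam difference of glcG without dnd rests on 7 counts in WT and 22 in dam. That of sodA with dnd rests on 26 in dnd and 46 in dnd_dam. Both pairs lie below the limit of 50 counts for a comparison of libraries, which any library could meet here.

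The block of 94 genes at 0 in both dnd libraries is the widest difference in the series. Depth is argued against by the 26965 counts that the WT level predicts for the block in the dnd library, and loss of reads to shared copies or a filter by the 93 block genes above 0 in both WT and dam. Lower transcription as deep as the deepest of any single gene elsewhere (srpA) would still leave 130 counts in dnd. Absence of a mobile element from both dnd strains is a candidate explanation: the block begins with a recombinase gene, which holds at either end of only 0.449% of 5346 windows of as many genes. A deeper silencing of the whole block stays open, as does whether both dnd strains descend from 1 colony, since no DNA was analysed here.

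The run of 9 genes from mfeA to pbuA was high in WT alone. Scaling is argued against by the median closest to 0 over 3 scalings and 3 comparisons, -5.47, and a single over-amplified transcript by the 36.7% of the run's WT counts that its highest gene, srpA, held. A passing state of the single WT culture, or a difference in the WT stock, could give the same values as a response to either cluster and cannot be told apart from it with 1 WT library. The derivatives differed among themselves by a median of 0.79 log2 units over the run.

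The median of 31 TCA cycle genes was above WT in all 3 derivatives, with 28 members above it in dnd, 23 in dam and 29 in dnd_dam, while mqo1 (P.putida.S1GL003655) was lower in each (-3.51, -1.40 and -2.43). Scaling is argued against by the lowest of 9 list medians, 0.46. Slower growth of the dnd culture is a candidate explanation for its part, since at least 96.2% of ribosomal protein genes were lower there than in WT under each scaling. The TCA median was 0.90 in dnd and 0.54 in dam, where the ribosomal protein median was 0.06. In dnd_dam the TCA median was 0.84 and the ribosomal protein median -0.02. Slower growth of the dnd culture alone would therefore leave the dam and dnd_dam values unexplained. In dnd_dam against dnd, the ribosomal protein median was 0.38, while the TCA median was not below 0 (0.17, or 0.005 by library size alone). Compared gene by gene, the median log2 ratio of dnd to dam over the 31 genes was -0.05. For dam and dnd_dam, where at least 39.6% and 52.8% were lower, this cannot be told apart from other explanations, because no growth data were analysed here and the single WT library enters every comparison. A response to the introduced clusters themselves also stays open and was not tested.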

How the results depend on the processing

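The settings without the block and beyond the counting interval, and library size alone for lists, were chosen after the data were seen. Over all settings 130 of 168 gene counts stayed within 1.5 times their value. The balance of higher and lower genes turned for dam against WT under library size alone (158 and 117, then 121 and 135) and with no low-count filter (192 and 239), for dnd against WT with no low-count filter (323 and 252, then 374 and 378), and for dnd_dam against dam without the block (100 and 152, then 100 and 81). List medians under DESeq2 size factors, FPKM, without the block and with lists as matched, 528 in all, moved by less than the interquartile range of their members. That limit is wide, since medians that changed sign also stayed within it, and library size alone was not among these settings. DESeq2 size factors, FPKM, both other prior counts and leaving out the 10 genes with the most counts moved 0 gene counts. The FPKM constants of the libraries were low where the TMM factors were high, so FPKM carries nearly the same scaling. Its agreement is therefore no separate check of the scaling. At 4-fold, higher and lower genes numbered 98 and 96 for dnd against WT, 25 and 16 for dam against WT, 41 and 102 for dnd_dam against WT, 8 and 24 for dnd_dam against dnd, 20 and 80 for dnd_dam against dam, and 33 and 50 for the interaction. Genes past 4-fold both without and with the other cluster were 20 for dnd (higher) and 4 and 2 for dam (higher and lower). Beyond the counting interval the counts in the same order were 214 and 153, 88 and 48, 145 and 181, 37 and 100, 53 and 99, and 65 and 121; both limits are stricter by construction. With no low-count filter, lower genes also numbered 522 for dnd_dam against WT, higher and lower genes 129 and 316 for dnd_dam against dnd and 165 and 292 for dnd_dam against dam, and higher genes 308 for the interaction, through genes with few counts. Library size alone gave 50 higher genes for dnd_dam against dnd. It moved the median log2 ratio outside the block from -0.01 to -0.17 and left the standard deviation at 0.571, so all ratios shifted together. Without the block, dnd_dam against dam had 81 lower genes. Genes lower with dnd both without and with dam numbered 116 with the block, 38 without it and 72 with a mean of at least 50 counts, since fewer genes were compared. Of 978 values of named genes 928 moved by less than their counting interval. Of the others, 22 under FPKM and 22 under a prior count of 5 are of block genes at 0, whose fitted value depends on the unit and the prior count, and 6 are of sucD, ilvC, STOM and rtcB under library size alone. In these 4 settings, list medians changed sign 7 times, for type II and III secretion, fatty acid, prophage and exopolysaccharide genes, all with values between -0.13 and 0.08. Under library size alone, 20 of 132 changed sign, the largest for respiration in dnd_dam against dnd, from 0.16 to -0.01. Of 132 list percentiles, 52 lay past 2.5 or 97.5 among random lists; among shifted lists, 8 of these did not and 5 others did. Fits of 2 groups only, DESeq2 per group and leaving out a column were not run, since each leaves 0 residual degrees of freedom. The labels give no replicate number for a block, and camera and fry were left out. No paired analysis was possible because the labels give 1 library per genotype and no replicate number shared between genotypes.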

Other observations

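The neighbour runs below and the additive model were chosen after the data were seen. Genes at least 4-fold higher in dnd than in WT often lay side by side: 12 runs of 3 or more such genes held 50 genes. Besides the glc and sulfur genes, they included genes of glycine and serine breakdown (gcvT, sdaA, gcvP1 and gcvH1, median log2 ratio 2.93) and the arginine deiminase genes arcC, arcB and arcA (2.26 over the run). Others were the genes of a cbb3 oxidase, which serves respiration at low oxygen (ccoP2 to ccoN1, 2.67), and a transport system for basic amino acids (argT, hisQ, hisM and hisP, 2.66 over the run). The latter run also held P.putida.S1GL003570, which shares the symbol arcB but is matched to an ornithine cyclodeaminase. The run with the glc genes ended in solI, matched to an acyl-homoserine-lactone synthase of cell-to-cell signalling, with 49, 363, 31 and 36 counts in WT, dnd, dam and dnd_dam. On the lower side lay ycgL, rtcB and STOM (median -2.61), and in dnd_dam this run took in 6 genes from gltR to STOM (median -2.71).

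The genes of this paragraph were picked after their values were seen. The short-chain fatty acid transporter gene atoE was lower in WT than in each of the 3 derivatives by at least 4-fold: it had 88, 809, 789 and 579 counts in WT, dnd, dam and dnd_dam, and its neighbours lpsJ and scoA followed it. The acetate symporter gene actP (P.putida.S1GL003917: 203, 1500, 863 and 1208), the succinyl-CoA:coenzyme A transferase gene cat1 (403, 1942, 2021 and 2050), bcd and osmY (P.putida.S1GL004543) did the same. Among genes whose other libraries lay within 2-fold of one another, 9 were lower and 8 higher in WT than in every other library by at least 4-fold, 8 were higher and 2 lower in dnd, 0 were so in dam, and 1, the export gene emrB, was lower in dnd_dam. The pair lower in dnd were the neighbours HI_0183, a transporter gene (4198, 417, 3943 and 2314), and ansA (734, 113, 739 and 571).

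An additive model that assumes no interaction leaves 1 residual degree of freedom over the 4 libraries. Its p-values rest on that assumption, while 171 and 297 of 4310 genes had an interaction at least 2-fold higher and lower. Its dnd term cannot be told apart from effects of the block at 0. Over 4232 genes outside the block, its dnd term had 32 genes higher and 15 lower at an adjusted p of 0.05 by edgeR's quasi-likelihood test (561 at an unadjusted p of 0.05) and 73 and 23 by DESeq2. Its dam term had 2 higher and 3 lower by edgeR (429 unadjusted) and 21 and 12 by DESeq2. Over all 4310 genes, edgeR gave 36 higher and 94 lower for dnd and 0 and 1 for dam (617 and 398 unadjusted), and DESeq2 gave 74 and 50 for dnd and 25 and 17 for dam. The genes with the smallest p for dnd in edgeR included arcB (P.putida.S1GL003570), with a log2 difference of 3.55 (adjusted p = 0.00217, higher in both dnd libraries), modE at 3.43, ssuA at 3.45, the sulfate-binding protein gene sbp at 2.68, and STOM and rtcB at -2.88 and -2.66. For dam, norM stood at -3.47 (adjusted p = 0.00306 in edgeR, lower in both dam libraries). The common biological coefficient of variation of this fit was 0.224, which includes any interaction.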
